A study of Homo sapiens with 6 samples.

How the data were processed

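H3K27ac, the histone mark of active promoters and enhancers, was profiled by chromatin immunoprecipitation and sequencing (ChIP-seq) in 3 human multiple myeloma cell lines. The lines were KMS-11, KMS-12 and RPMI8226. Each line was grown with DMSO, the solvent control, or with JQ1, a small molecule that blocks the acetyl-lysine pocket of the BET bromodomain proteins. JQ1 was given at 1 µM for 72 h, per the labels' treatment field. The labels give 6 samples, 1 per line and treatment, so that each group held 3 samples and the line tied each JQ1 sample to its DMSO sample. The antibody was a Diagenode H3K27ac antibody, per the labels.

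The analysis started from 1 table of 838 regions. For each region it holds a position, the number of cell lines in common (2 or 3) and 1 log fold change (LFC) per cell line, computed by the authors before deposition. DESeq2 and MACS2 and the genome builds hg38 and GRCh38.p13 appear in the submitters' processing notes with no role. The aligner, the peak settings, the normalization between libraries, the thresholds and the strand of any step are not given in the sources used here. The deposited values were read as log2 fold changes of JQ1 over DMSO. Neither the log base nor the numerator is written in the file, per the file headers. DESeq2, which the submitters' notes name, reports log2 values, and every statement below that H3K27ac was lower after JQ1 rests on that reading. The table holds no count, signal, standard error or p-value, and no value of a single sample, so depth per sample is unknown and no error can be attached to a fold change.

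The filter behind the table was tested on its values. All 838 regions had 3 values below 0. In all 838 the number of lines in common equalled the number of values below -0.5, and the weakest second-lowest value was -0.50. The list therefore contains regions past -0.5 in at least 2 lines and below 0 in the other. It shows nothing about regions that rose or did not pass, and the peaks from which it was drawn were not used here. Since the rule fixes the direction, the split of direction was not tested. A fit over the 6 samples and a rescaling of libraries, both planned before the data were examined, could not be made without values per sample.

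Regions were placed on the RefSeq gene table of GRCh38.p14, whose chromosome coordinates are those of hg38. The table gave 20052 protein coding and 18330 lncRNA genes with a start and an end, but no strand, exon or transcript. The planned distance to a transcription start was replaced by the distance to the nearer gene boundary (either end of a gene). A region was assigned to every protein coding or lncRNA gene whose body it overlapped, or, where it overlapped none, to the gene with the nearest boundary. This gave 1029 genes, 824 protein coding and 205 lncRNA. Positions are printed as the file gives them.

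The share of regions within 1 kb of a gene boundary was compared with 1000 sets of regions of the same widths placed at random on the same chromosome, between its first and last gene boundary. For 16 gene lists fixed before the data were examined, a two-sided Fisher exact test compared the share of assigned genes with a region past -0.5 in all 3 lines (against 2 lines) between list members and the other assigned genes, with Benjamini-Hochberg adjustment over the 16 lists. A gene with several regions counted as past -0.5 in all 3 lines if any of its regions was. The lists were fixed beforehand, but the plan did not name this contrast of 3 with 2 lines. Fold changes near and far from gene boundaries were compared as a difference of medians with a permutation test of 100000 resamples across regions, or 20000 for single lines, and a 95% bootstrap interval from 10000 draws. Spearman's rho and Pearson's r between the lines' fold changes were computed across regions, with permutation tests of 100000 resamples and adjustment over the 3 pairs. Regions and genes are not independent replicates, so these tests describe the list and not variation between cultures. Because the filter itself ties the lines to each other, rho was also computed in the 213 regions past -0.5 in all 3 lines, and against permutations made within the 4 classes of lines past -0.5 (20000 resamples). On simulated lists filtered in the same way, independent lines gave a mean rho of -0.23. The permutation within classes called 7% of 200 such lists of 838 regions at 0.05, and 96% of 200 lists drawn with a correlation of 0.5. In separate checks without the filter, 100% of 200 genes were assigned from regions planted over them, which tests only the code. Simulated values lowered by 0.2 in a subset, also unfiltered, gave an estimated difference between medians of -0.18.

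The text names SMILO, FLI1 and MYC in any case, the 10 regions with the lowest mean fold change over the 3 lines, and up to 4 members per fixed list by the same mean. One of the 10 regions is not reported here. Other genes were named after their values were seen, as stated there. A list of snoRNA host genes, assembled from the genes of the listed regions, was tried and left out because its members had been chosen from the result. Alternatives were stricter thresholds, other distances and widths, merging of regions within 12.5 kb, other gene assignments and backgrounds, and the removal of each cell line. The stricter adjusted p, the fits per sample and the split by mean level were not run, since the table lacks those values. Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9 were used.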

Results

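Changes of H3K27ac after BET inhibition were available as 838 genomic regions with 1 log2 fold change per myeloma cell line. KMS-11, KMS-12 and RPMI8226 are established human multiple myeloma (malignant plasma cell) lines. Each contributed 1 DMSO and 1 JQ1 sample, for 3 samples per treatment, and no replicate within a line. Sequencing depth is unknown because the table gives no counts, and fold changes are therefore printed without an error. The 838 regions were 332 to 3484 bp wide, with a median of 1164 bp, and covered 1048 kb on 23 chromosomes. None overlapped another.

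The first question was which H3K27ac regions were lower after 1 µM JQ1 for 72 h in several myeloma lines. The authors' deposited table listed 213 regions past a log2 fold change of -0.5 in all 3 lines and 625 past it in 2 lines. Of the regions shared by 2 lines, 299 were past -0.5 in KMS-11 and KMS-12, 187 in KMS-11 and RPMI8226, and 139 in KMS-12 and RPMI8226. Over all regions of the authors' deposited table the median log2 fold change was -0.66 in KMS-11, -0.69 in KMS-12 and -0.56 in RPMI8226, which on the log2 reading is 36.9%, 37.9% and 32.3% less signal. Values below -1 were listed for 113 regions in KMS-11, 178 in KMS-12 and 37 in RPMI8226 in the authors' deposited table. KMS-12 had the lowest value of the 3 lines in 374 regions, KMS-11 in 283 and RPMI8226 in 181. Because the list was filtered on these same values, neither the direction nor the number of regions was tested, and the differences between lines carry no replicate check. Only 62 regions were below -1 in at least 2 lines. Both remaining lines were past -0.5 in 352 regions without KMS-11, 400 without KMS-12 and 512 without RPMI8226.

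**Figure D1:**
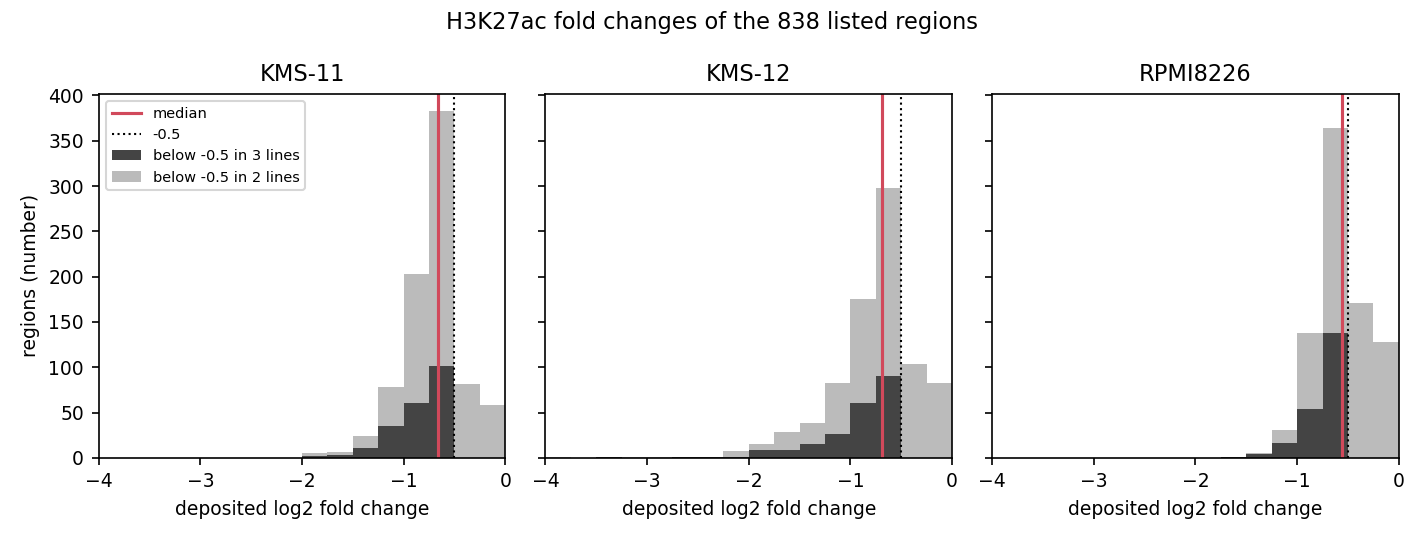
Histograms of the deposited log2 fold change (x axis) of the 838 regions in each cell line, as numbers of regions (y axis), with regions past -0.5 in 3 lines in dark grey and in 2 lines in light grey. Solid lines mark the medians of -0.66, -0.69 and -0.56, the dotted line marks -0.5, and the long left tail belongs to KMS-12.

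The region with the lowest mean value lay over TRIB3, a pseudokinase gene induced by cell stress (chromosome 20, 379892 to 381875). The authors' deposited table gave it -1.53 in KMS-11, -3.42 in KMS-12 and -0.97 in RPMI8226. Another covered CEBPB, which encodes a stress- and inflammation-responsive transcription factor (chromosome 20, 50190838 to 50193176). Its values in the authors' deposited table were -1.07, -3.86 and -0.37 in the same order of lines, so RPMI8226 was not past -0.5. A region of chromosome 19 from 14247789 to 14249277 was also among the lowest, outside any gene and 41620 bp from the boundary of ADGRL1, with -1.57, -1.96 and -1.25 in the authors' deposited table. Inside TCEA1, which encodes a transcription elongation factor, and the readthrough gene LYPLA1-TCEA1, the authors' deposited table listed -1.10, -2.43 and -1.06 (chromosome 8, 54019875 to 54020579). A region in CLIP1 (chromosome 12, 122406187 to 122407587) had -1.27, -2.68 and -0.56 in the authors' deposited table. RGS16, a regulator of G protein signalling, was covered from 182603583 to 182604446 of chromosome 1, and the authors' deposited table gave -1.91, -1.48 and -0.90. Values in the authors' deposited table were -1.14, -1.96 and -1.14 at HAGHL (chromosome 16, 727170 to 728185). They were -1.59, -2.22 and -0.42 at the uncharacterised lncRNA LOC124903862 (chromosome 1, 17440157 to 17442084) in the authors' deposited table. ACTG1, the gene of cytoplasmic gamma-actin, had -1.96, -1.46 and -0.73 in the authors' deposited table (chromosome 17, 81512315 to 81514762). In 7 of these 9 regions all 3 lines were past -0.5.

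The series addresses the lncRNA SMILO and the ETS transcription factor FLI1. One listed region lay inside FLI1, at 128693479 to 128695455 of chromosome 11, and also inside SENCR, an lncRNA gene that overlaps it. The authors' deposited table gave this region -0.62 in KMS-11, -0.58 in KMS-12 and -0.28 in RPMI8226, so that it counted as shared by 2 lines. Reads of the region cannot be divided between FLI1 and SENCR. SMILO carries the RefSeq symbol LINC00582 (chromosome 1, 231591292 to 231612090). No listed region overlapped it, and the nearest, at MAP3K21, was 1.72 Mb away. MYC, an oncogene well known as a target of BET inhibition in myeloma, also had no listed region, the nearest being 3.36 Mb away at TMEM65. A locus without a listed region did not meet the filter or was not tested, and the table cannot separate these.

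Plasma cell regulators were represented by 2 of 20 list members, both past -0.5 in all 3 lines. IRF4, a transcription factor on which myeloma cells depend, had -1.10 in KMS-11, -1.81 in KMS-12 and -1.07 in RPMI8226 in the authors' deposited table (chromosome 6, 391794 to 393844, inside the gene and 42 bp from its boundary). XBP1, the transcription factor of the secretory and unfolded protein response, had -1.08, -0.57 and -0.55 in the authors' deposited table (chromosome 22, 28798632 to 28801196, across a gene boundary). Among 20 ETS family genes, FLI1 and ERF had a region, and the authors' deposited table gave ERF, an ETS repressor, -0.75, -0.95 and -0.95. Both lists were too small to show a difference between 3-line and 2-line regions from the other genes (two-sided Fisher exact test, adjusted p = 0.529 and 1).

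One fixed list, that of the endoplasmic reticulum (ER) and the unfolded protein response (UPR), the program by which secretory cells fold and clear proteins, passed the comparison of 3-line with 2-line regions. Of its 32 annotated members, 12 had a listed region, and 9 of the 12 had a region past -0.5 in all 3 lines. TRIB3, counted among the 9, also had a region past it in 2 lines only (chromosome 20, 402151 to 402523). The share in 3 lines was 75% against 25.2% of the other genes (two-sided Fisher exact test, p = 4.6e-04, adjusted p = 0.00736 over 16 lists). After TRIB3 the lowest members were SEL1L, ERN1 and DDIT3. SEL1L, part of the ER-associated degradation complex, had -1.30 in KMS-11, -1.85 in KMS-12 and -0.85 in RPMI8226 in the authors' deposited table (chromosome 14, 81529773 to 81530433, inside the gene). The authors' deposited table listed -0.99, -1.37 and -1.37 for ERN1, the sensor that splices XBP1 mRNA (chromosome 17, 64128938 to 64130117), and -0.78, -1.48 and -0.63 for DDIT3, the stress transcription factor CHOP (chromosome 12, 57519459 to 57520523). The other members past -0.5 in 3 lines, named after their values were seen, were SEC61A1, EDEM1, ATF4, DNAJB9 and HERPUD1, and those past it in 2 lines were PDIA4, CALR and DNAJC3. The call depended on the choice of lines. Requiring both remaining lines kept 12 of 12 members without KMS-12 (adjusted p = 0.00272, Fisher exact test), but 9 of 12 without KMS-11 (adjusted p = 0.29) and 9 of 12 without RPMI8226 (adjusted p = 1), when 42.5% and 60.4% of the other genes also passed. The line left out had still helped to choose the listed genes. These tests therefore show which lines the members shared, and not whether the call holds without a line.

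**Figure D2:**
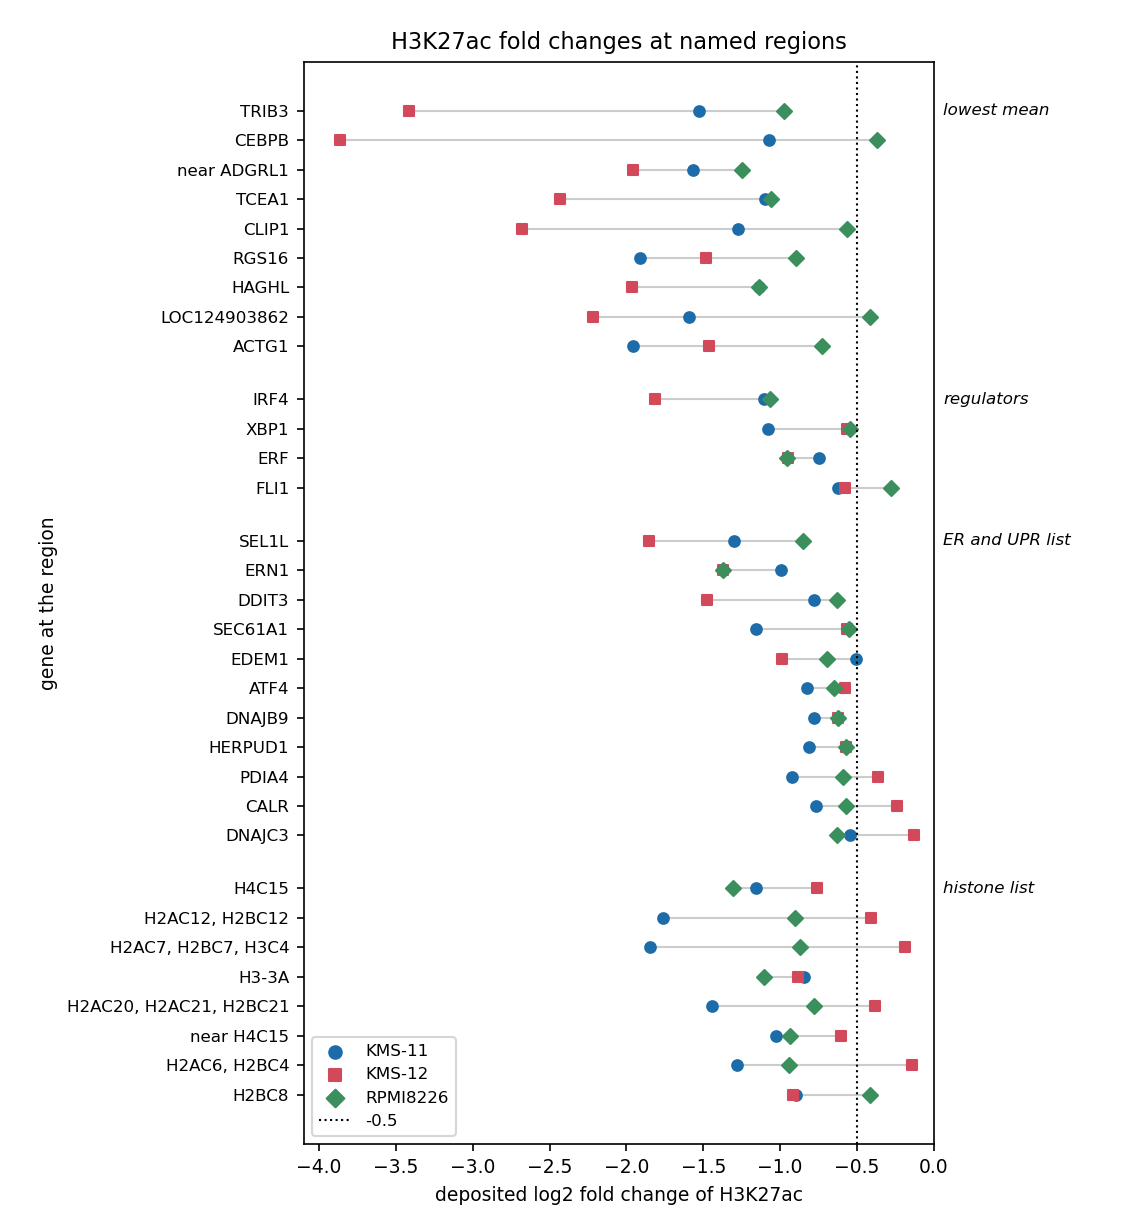
Deposited log2 fold changes (x axis) at named regions, 1 row per region labelled by its gene, with circles for KMS-11, squares for KMS-12 and diamonds for RPMI8226, and a dotted line at -0.5. TRIB3 is shown among the regions of lowest mean and not again with the ER and UPR list, and the squares lie far left at TRIB3 (-3.42) and CEBPB (-3.86) but near 0 at H2AC7, H2BC7 and H3C4 (-0.18).

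Histone genes had regions at 19 of 92 members (20.7%, against 4.03% of the other protein coding genes, two-sided Fisher exact test, adjusted p = 4.0e-08). In the same test the ER and UPR list had 37.5% against 4.06% (adjusted p = 3.6e-08, Fisher exact test), and no other list passed it. Genes of 1 histone cluster share regions, so they are not independent, and which background genes could have entered the list is unknown. Of the 19 histone genes, 2 were past -0.5 in all 3 lines and 17 in 2 lines, a share of 10.5% in 3 lines against 26% of the other genes (two-sided Fisher exact test, adjusted p = 0.981 over 16 lists). The lowest were at H4C15 and at the clusters that hold H2AC12 with H2BC12 and H2AC7 with H2BC7 and H3C4. The authors' deposited table gave H4C15 -1.16 in KMS-11, -0.76 in KMS-12 and -1.31 in RPMI8226 (chromosome 1, 149849364 to 149850685). The gene boundary nearest to this region was that of H2AC19, 376 bp away. When every gene within 1 kb was assigned, 4 of 23 histone genes were past -0.5 in all 3 lines. The H2AC7 cluster region of chromosome 6, 26198299 to 26200193, had -1.85, -0.18 and -0.87 in the authors' deposited table. Some histone genes have near-identical copies, and how reads shared between such copies were counted is not given in the sources used here. Members with such copies are therefore uncertain, and which members these are was not examined.

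Apart from the lncRNA list, the remaining lists had few members among the regions, and no list other than the ER and UPR list passed the 3-line test after adjustment. The surface and secreted protein list had 3 of 35, namely MZB1, BMP6 and IGF1R. MZB1, a chaperone of antibody-secreting cells, had -1.40 in KMS-11, -0.99 in KMS-12 and -0.07 in RPMI8226 in the authors' deposited table. Myeloma oncogenes and tumour suppressors had 3 of 34, namely PIM3, NSD2 and H1-4, and the authors' deposited table gave the kinase gene PIM3 -0.67, -1.35 and -0.56. The NSD2 region lay 409 bp outside that gene. The MYC list had MXI1 and MNT, both antagonists of MYC, the BET-responsive list had RGS16 and AFF1 of 21, and the apoptosis list had BBC3 of 19. The lncRNA list, which held LINC, -AS1, -DT and -IT1 symbols and a few named genes rather than all annotated lncRNA genes, had 91 of 4794, 21 of them in 3 lines. Against all annotated genes this was 1.90% compared with 2.79% of the others (two-sided Fisher exact test, adjusted p = 0.00121). Those others include the protein coding genes, of which 4.11% had a region. Among all 18330 annotated lncRNA genes 205 had one, so the test does not show fewer regions at the list than at other lncRNA genes. The lowest were CEBPB-AS1, which shares its region with CEBPB, BHLHE40-AS1, and LINC01719 and LINC01473, whose regions lay 13248 and 43441 bp outside them. BHLHE40-AS1 had -1.22, -1.60 and -0.57 in the authors' deposited table. The NF-kB list of 28 genes, the cell cycle and replication list of 29, and the B cell (12), T and NK cell (12), myeloid (11) and stromal and endothelial (10) marker lists had 0 members among the assigned genes. With 4.11% of protein coding genes assigned, lists this small cannot show an absence. Against the other protein coding genes, the 2 largest had p = 0.629 (NF-kB) and 0.632 (cell cycle, two-sided Fisher exact tests). When every gene within 1 kb was assigned, the cell cycle list had 1 member.

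**Figure D3:**
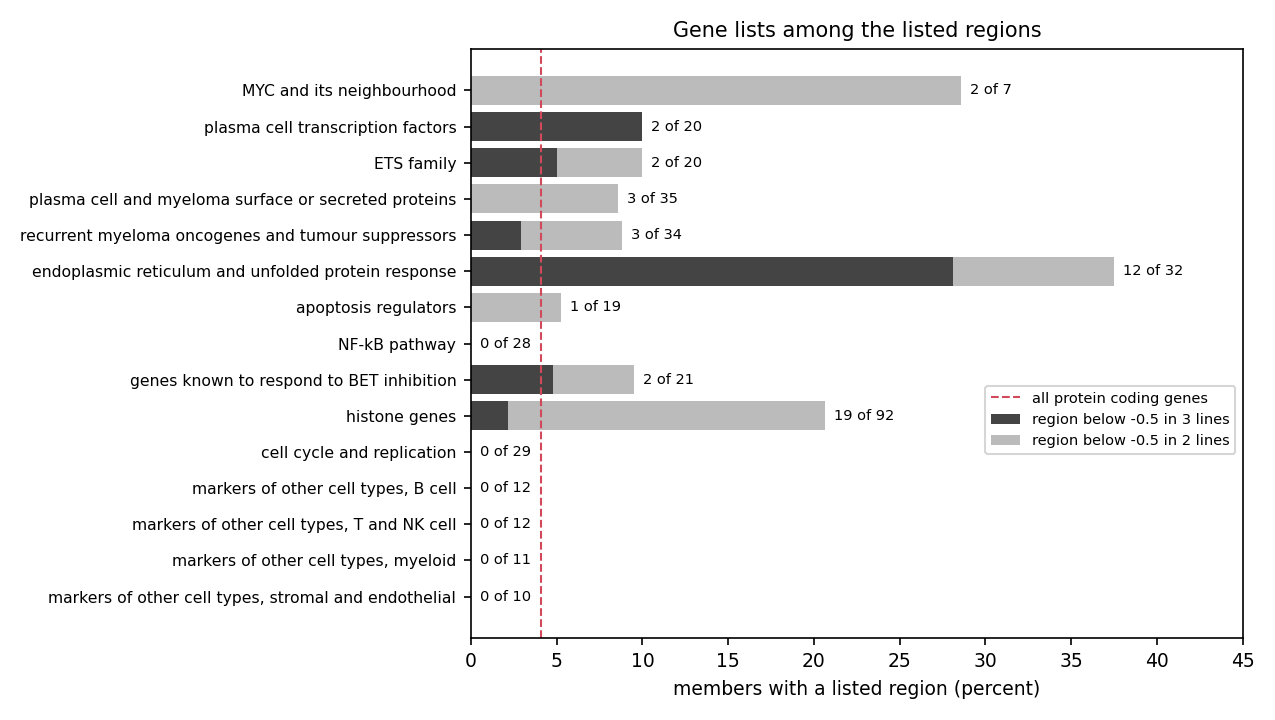
Percent of the annotated members of 15 fixed gene lists with a listed region (x axis), with the number of members beside each bar. Dark grey marks members with any region past -0.5 in 3 lines, and light grey those with regions past it in 2 lines only. The dashed line is the share of all protein coding genes (4.11%), and the longest bar is the ER and UPR list at 37.5%.

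The next question was where the regions lay. Of the 838 regions, 654 (78.0%) were within 1 kb of a gene boundary, 422 (50.4%) overlapped one, and 757 (90.3%) overlapped a gene body. Randomly placed regions were within 1 kb in 8.06% ± 0.92 (SD of 1000 sets), and the observed share was above all of them (permutation p = 0.001, the smallest that 1000 sets can give). H3K27ac marks active promoters and the placements did not favour genes, so any list of H3K27ac regions would be likely to exceed them. Whether the listed regions lay nearer to genes than other H3K27ac regions was not tested. Of the 184 regions further away, 58 lay outside gene bodies. Start and end of a gene could not be told apart without strand.

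Regions near a gene boundary were compared with those further away to ask whether fold changes within the list differed with this distance. All regions had passed the same filter, so the comparison cannot show whether promoter-proximal and distal H3K27ac moved alike. Near regions may also lie at the end of a gene rather than at its start. In the authors' deposited table the median of the mean fold change was -0.62 in 654 near regions and -0.65 in 184 far regions. The difference of 0.0294 had a 95% bootstrap interval of -0.0139 to 0.0710 and a two-sided permutation p of 0.0454 across regions, so the interval included 0 although the permutation p was under 0.05. With a limit of 2.5 kb it was 0.0130 (p = 0.416, permutation test). By line, the far regions of the authors' deposited table were lower in KMS-12 (median -0.76 against -0.67, difference 0.0846, interval 0.0232 to 0.188, adjusted permutation p = 0.0274 over 4 tests), while the differences were 0.0261 in KMS-11 and 0.0120 in RPMI8226 (adjusted permutation p = 0.451 and 0.633). At 2.5 kb the KMS-12 difference was larger, 0.128 (interval 0.0271 to 0.236, adjusted permutation p = 4.0e-04). Without KMS-12 the difference of the mean was -0.00664 (p = 0.79, permutation test), without KMS-11 0.0568 (p = 0.00675, permutation test) and without RPMI8226 0.0518 (p = 0.0138, permutation test). The share of regions past -0.5 in 3 lines was 25.8% near and 23.9% far (two-sided Fisher exact test, p = 0.633).

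The last comparison asked whether the regions lowest in one line were also lowest in another. Across all 838 regions of the authors' deposited table, Spearman's rho was 0.0782 for KMS-11 and KMS-12, -0.0945 for KMS-11 and RPMI8226 and -0.249 for KMS-12 and RPMI8226, with adjusted permutation p-values of 0.0242, 0.00903 and 3e-05 (1e-05 before adjustment, the smallest that 100000 resamples can give). Pearson's r was 0.186, -0.0645 and -0.179 in the same order (adjusted permutation p = 1.5e-05, 0.0627 and 1.5e-05). The filter, which asks for 2 lines past -0.5, can produce negative values by itself (mean rho of -0.23 on simulated independent lines). The classes of lines past -0.5 come from the same fold changes. Permutation within them therefore cannot separate the filter from opposed responses of the lines. Permutation within the 4 classes of lines gave mean rho of -0.0233, -0.129 and -0.262, and the observed rho exceeded these for the pairs with KMS-11 (adjusted permutation p = 1.5e-04, the smallest possible here, and 0.0198) but not detectably for KMS-12 and RPMI8226 (0.311). In the 213 regions past -0.5 in all 3 lines, rho was 0.216, 0.171 and 0.0898 (adjusted permutation p = 0.0048, 0.0181 and 0.191), and r was 0.394, 0.225 and 0.181 (adjusted permutation p = 3e-05, 0.00144 and 0.00916). All 838 regions had the same sign in the 3 lines, as the filter requires. These are correlations across regions within 1 set of libraries, and regions are not independent replicates.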

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

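Each deposited fold change already pairs JQ1 with DMSO within a line, and no test of direction across the 3 lines was made, because the filter fixes the sign in every region. No fit per sample, rescaling of libraries, stricter adjusted p or split by mean level was run, because the table holds no p-value and no value of a single sample. The removals of single lines (except those for the mean rho, which were planned), the 213-region and within-class settings, the 1 kb assignment and the protein coding background were chosen after seeing the data. The plan set a Fisher exact test of the fixed lists but did not name the contrast of 3-line with 2-line regions. That contrast could be set only once the number of lines per region was known. The list of 838 regions shrank to 62 with a log2 fold change below -1 in at least 2 lines, and to 352 (without KMS-11), 400 (without KMS-12) and 512 (without RPMI8226) regions past -0.5 in both lines that remained after 1 was left out; counted as genes it was 1029. The share near a gene boundary stayed above random placement in all 7 alternatives run, which is likely for any list of H3K27ac regions and tells nothing particular about those lower after JQ1. In the 3-line test 1 of 16 lists passed, 1 under each of 2 other assignments and 0 to 1 with 1 line left out. Tests of having any listed region ask another question. Against all annotated genes 3 lists passed (histone and ER and UPR genes above the others, and the lncRNA list below others that include the protein coding genes). Against protein coding genes 2 did (histone, ER and UPR). Which of those background genes could have entered the list is unknown. The log2 odds of the ER and UPR list, 3.01, was 0.83 without RPMI8226, 1.88 without KMS-11 and 4.75 without KMS-12, and it kept its call under 2 other assignments (adjusted p = 0.00919 and 0.0301, Fisher exact test). A line left out had still helped to choose the listed genes, so these removals cannot show whether the call holds without it. Spearman's rho of KMS-11 and RPMI8226 turned from -0.0945 to 0.171 in the 213 regions and to 0.0350 above its mean under permutation within classes, and rho of KMS-12 and RPMI8226 from -0.249 to 0.0898 and 0.0130. The filter can give negative values by itself, so those over all regions cannot be read as opposed responses. Whether it accounts for them in full cannot be told, because the classes come from the same fold changes. The mean rho of the 3 pairs, -0.0883, was -0.249 without KMS-11, -0.0945 without KMS-12 and 0.0782 without RPMI8226. The difference near and far from gene boundaries, 0.0294, was 0.0130 at 2.5 kb and ranged from -0.00664 (without KMS-12) to 0.0568 (without KMS-11); the cause was not tested. Depth is unknown, so no fold change can be weighed by it.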

Other observations

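The 4 lists used here beyond the fixed ones, and all tests below except those of gene length, were chosen after the regions' genes or values had been seen, so their counts are not independent evidence. The ATF4 list in particular was written with the regions' genes in view, so its share of genes with a region was partly built in.

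Genes of amino acid supply and the integrated stress response, the program driven by the transcription factor ATF4, were among those with regions. Of 56 such protein coding genes, 29 had a listed region (51.8%), against 3.98% of the other protein coding genes. They included the amino acid transporters SLC7A5, SLC3A2, SLC1A5, SLC1A4, SLC38A2 and SLC6A9, and the serine, proline and cysteine synthesis genes PSAT1, PYCR1, ALDH18A1 and CTH. Others were SHMT2, a gene of serine and glycine metabolism, and the stress regulators ATF4, DDIT4, SESN2 and CHAC1. SLC7A5 had -0.82 in KMS-11, -1.38 in KMS-12 and -0.88 in RPMI8226 in the authors' deposited table. Of the 20 cytosolic aminoacyl-tRNA synthetase genes, a complete family, 4 had a region (AARS1, IARS1, SARS1 and WARS1). Of 20 genes on a glycolysis list, 5 had one (HK2, PFKP, PKM, LDHA and the transporter gene SLC16A3, which that list also held). Of 83 ribosomal protein genes, 8 had a region.

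Values by line are given for 3 gene groups. In the authors' deposited table the 30 regions of the ATF4 list had medians of -0.79 in KMS-11, -1.35 in KMS-12 and -0.43 in RPMI8226, and 19 of the 30 were past -0.5 in KMS-11 and KMS-12 only (63.3% against 34.7% of other regions). The 15 histone regions of the authors' deposited table had medians of -1.03, -0.54 and -0.71, with 7 of 15 past -0.5 in KMS-11 and RPMI8226 only (46.7% against 21.9% of other regions, adjusted p = 0.126 over 12 tests, Fisher exact test). The 14 ER and UPR regions had -0.79, -0.65 and -0.62 in the authors' deposited table. With 1 library per line and treatment, differences between the lines have no replicate check. Regions that overlap a tRNA gene numbered 10, of which 5 were past -0.5 in all 3 lines, against a mean of 0.185 and at most 2 in 1000 random placements (permutation p = 0.001, the smallest possible). These placements did not favour genes, although most listed regions lay near one, so an excess at tRNA genes beyond that of other H3K27ac regions was not tested. Chromosome 16 held 56 regions where its share of protein coding genes gives 35.8 (exact binomial test, adjusted p = 0.034 over 23 chromosomes). The number of all H3K27ac regions per chromosome is unknown, so an excess beyond that of other H3K27ac regions was not tested. The region furthest from any gene boundary lay on chromosome 4 from 49709356 to 49711895, 501 kb from the nearest, and had -1.71, -1.64 and -0.04 in the authors' deposited table. The aligner and the treatment of reads that map to several places are not given in the sources used here, so this single region is uncertain.

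A first pattern is the frequency of ER and UPR genes, 12 of 32. Gene length is argued against, since 10000 random lists of protein coding genes matched on length held 1.37 genes with a region on average and at most 7. Activity of the genes in general stays open: the share was higher than that of cell cycle and ribosomal protein genes (8 of 112, p = 8.0e-05, two-sided Fisher exact test), but not detectably higher than that of histone (19 of 92, p = 0.0952), glycolysis (5 of 20, p = 0.383) or synthetase genes (4 of 20, p = 0.228, all Fisher exact tests). Genes with strong acetylation before treatment may also enter such a list more readily, which the table cannot show. A lower acetylation of secretory-program genes in particular after JQ1 therefore stays a hypothesis beside these.

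A second pattern is the frequency of ATF4 list genes, 29 of 56. Because the list was written with the regions' genes in view, the tests run on it decide nothing about gene length (at most 12 in length-matched lists) or about active genes in general (p = 1.7e-10 against cell cycle and ribosomal protein genes, Fisher exact test). Only 6 genes were on both this list and the ER and UPR list, so the shared genes could never make up the count. Of the 29 genes with a region, 25 were not on the ER and UPR list, a description and no test. Gene length and general activity stay open, and no biological explanation was tested.

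The last pattern is the deep left tail of KMS-12. Noise of narrow regions is argued against, since the 38 regions where KMS-12 lay more than 1 below the mean of the other lines were wider than the rest by a median of 273.5 bp (95% bootstrap interval 95 to 430.0, permutation p = 0.0244). Read counts are unknown, so noise from low counts was not tested and stays open. A uniformly wider scale in KMS-12 stays open: at the histone regions, whose values had been seen, KMS-12 lay above the other lines (median distance below them -0.47, 95% bootstrap interval -0.72 to -0.09), and the difference from other regions, -0.61, had a permutation p of 5e-05 (the smallest that 20000 resamples can give, adjusted 7.5e-05) but a bootstrap interval of -0.88 to 0.07 that included 0. At the 14 ER and UPR regions no difference from other regions was detected (-0.12, 95% bootstrap interval -0.41 to 0.47, adjusted permutation p = 0.285). In regions of the ATF4 list KMS-12 lay further below the other lines than in other regions, by 0.55, but that list includes TRIB3 and CEBPB, whose KMS-12 values had been seen, so this is no test of a stronger response at such genes. That response and a difference of the single KMS-12 library pair also stay open.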
